A study of Homo sapiens with 8 samples.

How the data were processed

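Messenger RNA was sequenced in 8 libraries, 2 in each of 4 groups: A673 and UE7T-13, each with and without doxycycline. A673 is a human Ewing sarcoma line, and UE7T-13 is an immortalised line of human bone marrow mesenchymal stem cells. Both lines carried a piggyBac vector that expresses human SOX2 when doxycycline is present, and transfected cells had been selected with 2 µg/ml puromycin, per the labels' protocols. Treated cells received 1 µg/ml doxycycline for 3 h, and untreated cells received none. The labels do not say whether the 2 libraries of a group came from separate cultures, so every p-value measures only the spread between these samples. No library with doxycycline but without the SOX2 vector is among the samples, so an effect of SOX2 and one of doxycycline itself share the same comparison.

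The libraries were stranded and made from polyadenylated RNA, and were sequenced as 150 bp read pairs to about 12 Gb per sample, per the labels' protocols. Per the submitters' processing notes, base calling used CASAVA 1.8.4, reads were trimmed with Trimmomatic 0.36, aligned with HISAT2 2.1.0, and counted per gene with featureCounts of the Subread package, and DESeq2 was used for differential expression. The deposited count table holds raw counts, whole reads per gene with no scaling, for 60671 genes. The processing notes name hg19. The coordinates in the table match GRCh38 annotation instead: of 58453 gene identifiers found in GENCODE 29, 77.0% had the same start and end and 98.7% a start within 5000 bp. Coordinates are therefore given as the table has them, on GRCh38.

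For each cell line the authors also deposited a table of differential expression with mean normalised counts, log2 fold changes with standard errors, a Wald score, p-values and adjusted p-values. The sign of the deposited log2 fold changes is untreated over doxycycline, as the counts of SOX2 show, and it was turned before the comparison with the values here. These tables were used only to compare calls.

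Library totals ran from 43433187 to 52143970 counts. A count of 0 allowed up to 3 counts, which is 0.0575 to 0.0691 CPM (counts scaled to the library total) in a single library. Intervals and such floors cover counting error only, since reads were not marked with molecular identifiers. Folds against a group with 0 counts are lower bounds against 3 counts over the group.

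The test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with 1 fit over all 8 libraries, a mean for each of the 4 groups, TMM normalisation, and the filterByExpr filter at a minimum count of 10, which left 20946 genes. Sharing the fit leaves 4 residual degrees of freedom. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so single comparisons rest on the spread that edgeR shares across genes. The contrasts were doxycycline against none in A673, the same in UE7T-13, the difference between those effects, and untreated A673 against untreated UE7T-13. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene comes from this test unless another tool is named. Errors are standard errors (SE) of the log2 fold change, computed as its absolute value divided by the square root of the test's F statistic.

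For each contrast, 30 gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists that had at least 5 tested members. Camera with a correlation estimated from the data and fry were run beside it. The lists were the semenogelin neighbourhood, pluripotency network, neural progenitor genes, SOX family, EWSR1-FLI1 activated and repressed genes, mesenchymal stromal markers, osteogenic, chondrogenic and adipogenic genes, immediate early genes, WNT targets, the NOTCH pathway, YAP/TAZ targets, BMP and TGF-beta targets, FGF/ERK feedback genes, proliferation genes, p53 targets, doxorubicin resistance and drug efflux genes, ATF4 and integrated stress response genes, mitochondrially encoded mRNAs, glycolysis and hypoxia genes, unfolded protein response genes, interferon response genes, cholesterol biosynthesis genes, NF-kappaB and inflammatory genes, epithelial-mesenchymal transition genes, heat shock genes, replication-dependent histone genes, and epithelial, blood and immune, and endothelial markers.

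The groups, contrasts, lists, alternatives and the rule for naming genes were set before the data were examined. Under that rule SOX2, SEMG1 and SEMG2 are always named. For each doxycycline effect, the 14 higher and 14 lower called genes with the largest log2 fold change follow, among genes with a mean of at least 1 CPM in the higher group and both treated libraries beyond both untreated ones. For the difference and for the untreated lines the number is 10 per direction, and up to 4 called members per direction are named from each list. Unnamed identifiers, pseudogenes, newly annotated transcripts and antisense genes were counted but passed over when naming. Genes named outside the rule are said to be so.

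Alternatives were DESeq2 1.42.0, limma-voom, fits of only the 4 libraries compared, RLE and upper-quartile factors, library totals without a composition factor, no filter, a filter at 1 CPM in 2 libraries, a threshold of 1 on the log2 fold change, a block for the replicate number, each library left out in turn, SOX2 left out of the table, and every library thinned to the smallest total. Where a group was left with 1 library, that library was assumed to vary like the other groups. Offsets that remove each library's trend with GC content and gene length were added after seeing the data.

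On simulated counts for 20946 genes drawn from the real means and library sizes, the test recovered 80.6% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold in the A673 contrast, each over 66 or 67 changed genes. Of its 215 calls there, 32 were false, above the nominal rate. For UE7T-13 it recovered 82.1%, 91.0% and 100% at those folds, with 16 false of 198 calls, and for the difference 67.7%, 84.7% and 96.2%, with 24 false of 353. Camera called a raised list and 0 of 20 random lists. The simulated genes were drawn independently, so this does not test the preset correlation on lists whose members move together. For the A673 contrast the estimated correlation was 0.82 for mitochondrially encoded mRNAs and 0.73 for immediate early genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.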

Results

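Polyadenylated RNA of 8 libraries was compared, 2 in each of 4 groups: A673 and UE7T-13 cells that carry a doxycycline-inducible SOX2 gene, each untreated (DOX-) or 3 h after 1 µg/ml doxycycline (DOX+). The series asks how SOX2 acts in Ewing sarcoma cells, with the semenogelin gene SEMG1, proliferation and doxorubicin resistance as its named interests. The 4 A673 libraries held 52143970 and 49041908 counts untreated and 43502952 and 43433187 treated. The 4 UE7T-13 libraries held 47298522 and 45757076 untreated and 44815026 and 45089362 treated. The first principal component carried 95.3% of the variance and separated the cell lines. The median biological coefficient of variation over genes was 6.74%.

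SOX2, the induced gene, rose in both lines within 3 h. In A673 it went from 9652 and 10774 counts to 521825 and 564698, a 61.5-fold rise (log2 fold change 5.94, SE 0.10, adjusted p = 8.8e-15). In UE7T-13 it went from 3727 and 3903 counts to 121809 and 111173, a 30.9-fold rise (4.95, SE 0.10, adjusted p = 7.8e-14). The SOX2 gene (ENSG00000181449, chromosome 3, 181711925 to 181714436, plus strand) took 1.2% and 1.3% of all counts in treated A673, and 0.272% and 0.247% in treated UE7T-13. Counts per gene do not tell transcripts of the vector from those of the cells' own SOX2 gene. Its overlapping transcript SOX2-OT, which the vector does not encode, had 64 and 42 counts in untreated and 83 and 81 in treated A673, and was chosen for naming after its counts were seen. In UE7T-13 SOX2-OT had 2 and 1 counts untreated and 0 and 3 treated. Whether the cells' own SOX2 gene changed was not tested.

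SEMG1, which encodes the seminal gel protein semenogelin 1, rose 5.44-fold in A673, from 16 and 18 counts to 80 and 81 (log2 fold change 2.44, SE 0.38, adjusted p = 0.0016). It lies on chromosome 20 from 45207033 to 45209768 (ENSG00000124233, plus strand). All 4 UE7T-13 libraries had 0 counts of SEMG1, which allows up to 0.0164 CPM over them. A fall there, or a rise that stayed below this floor, could not be detected at this depth. A rise to the counts of treated A673, 80 and 81, was not seen there. The test of the difference between lines gave 2.44, the A673 value set against 0 counts, and did not call SEMG1. Whether its effect differs between the lines is therefore undecided. SEMG2, its neighbour, had 1 and 0 counts in untreated and 0 and 1 in treated A673 and was too low to test. Of the 14 genes listed for the semenogelin neighbourhood, SEMG1 alone passed the filter on low counts.

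**Figure D1:**
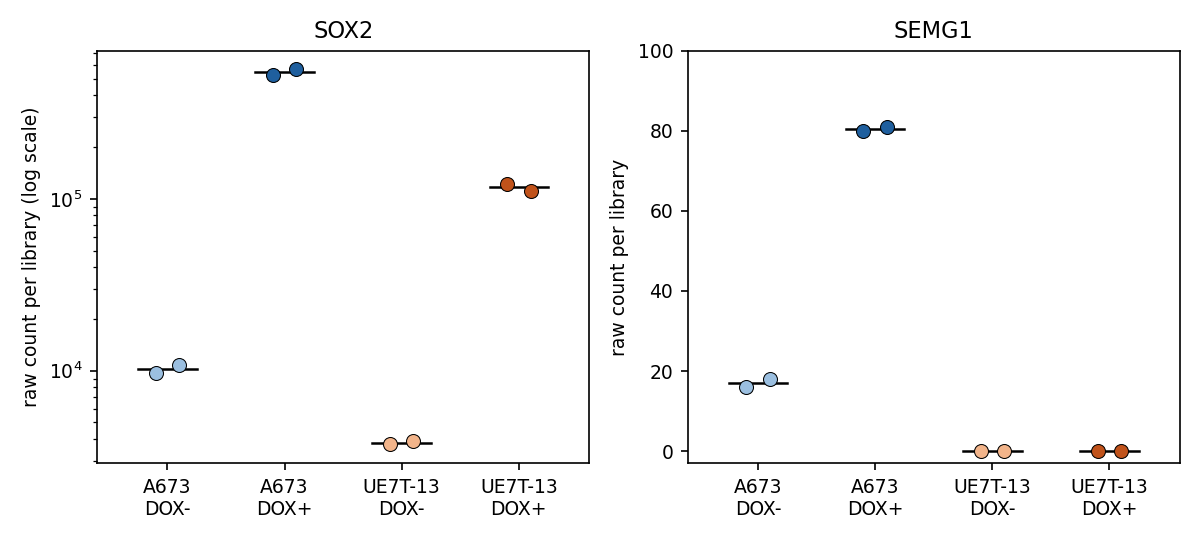
Raw counts of SOX2 (left, log scale) and SEMG1 (right, linear scale) in each of the 8 libraries; lines are group means. SOX2 counts rose in both lines, and SEMG1 went from 16 and 18 to 80 and 81 counts in A673 and stayed at 0 in UE7T-13.

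In A673 more genes fell than rose with doxycycline. IL11, a cytokine of the interleukin 6 family, fell by 2.83 on the log2 scale (SE 0.20), and CLCF1 of the same family fell by 1.90. SOCS3, a feedback inhibitor of cytokine signalling, fell by 1.82 (SE 0.13), the stress gene GADD45B by 1.99 (SE 0.11), and DUSP2, a phosphatase of MAP kinases, by 2.19 (SE 0.20). The adhesion scaffold NEDD9 (1.48, SE 0.06) and the innate immune receptor TLR4 (1.48, SE 0.23) rose beside SOX2 and SEMG1; in all 21 genes rose by a log2 fold change of at least 1, most of which the naming rule leaves out. TLR4 had 32 and 16 counts untreated against 65 and 51 treated.

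Other genes higher in treated A673 were the microRNA gene MIR7705 (0.93), the homeobox gene HHEX (0.92), TMEM100 (0.85), the protocadherin PCDH18 (0.81), SPRY1 (0.78), the aryl hydrocarbon receptor AHR (0.73) and CHAMP1 (0.71). LRRTM2 (1.15), LPAR6 (0.80) and SULT1A2 (0.73) were also called, but lost their call without A673 DOX+ replicate 1 (adjusted p = 0.166, 0.0664 and 0.223). LRRTM2 lost it also without A673 DOX- replicate 1, and LPAR6 and SULT1A2 without any 1 of the 4 A673 libraries. SULT1A2 was not called by DESeq2 either (0.73, adjusted p = 0.0635). Among genes lower in treated A673 were TINAGL1 (-2.21), TRIM47 (-1.91), BHLHE40 (-1.76), the inhibitor of NF-kappaB NFKBID (-1.76), the growth factor PDGFA (-1.69), the sphingosine kinase SPHK1 (-1.63), CSRNP1 (-1.6) and the mitochondrial tRNA gene MT-TV (-1.56). TAF11L11 (-1.58), 1 of several near-identical copies, lost its call without A673 DOX+ replicate 1 (adjusted p = 0.107), DOX+ replicate 2 or DOX- replicate 2. Reads of SULT1A2 and of MIR7705 cannot be told with certainty from those of a close paralog or an overlapping transcript.

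Altogether 332 genes were higher and 892 lower in treated A673, 270 and 788 of them protein coding. Most changes were small: the median log2 fold change was 0.31 for the higher and -0.47 for the lower genes, and 21 and 140 genes passed a log2 fold change of 1. Without A673 DOX+ replicate 1 the counts were 71 higher and 367 lower, and without A673 DOX- replicate 1 198 were higher. Fold changes in A673 also followed GC content, with a Spearman correlation of -0.436 across 11220 genes, and the 2 treated A673 libraries differed from each other along GC content as well (-0.531).

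**Figure D2:**
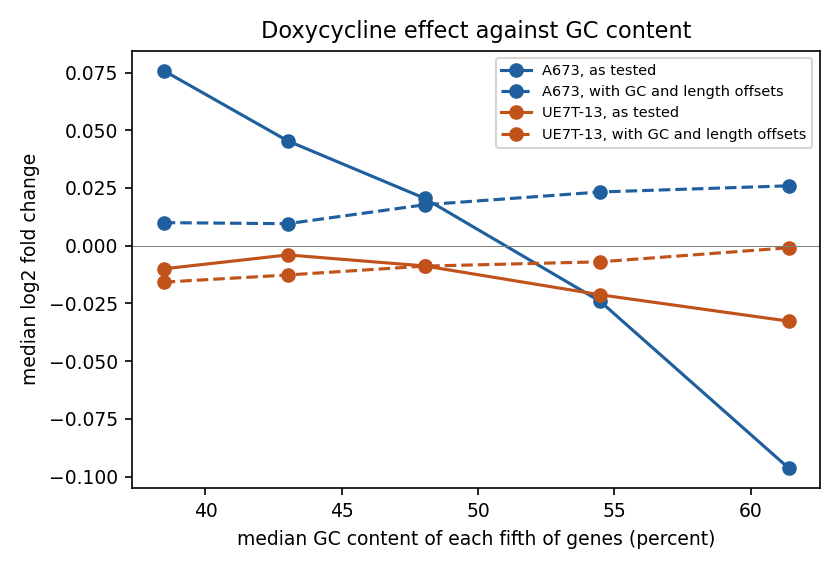
Median log2 fold change with doxycycline (vertical axis) in 5 equal groups of the 11220 well-measured genes by GC content in percent (horizontal axis), as tested (solid) and with GC and length offsets (dashed). In A673 the median went from 0.0758 in the group of lowest GC to -0.0963 in the group of highest GC, and UE7T-13 moved less.

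Immediate early genes, the first transcription factors and feedback genes to answer a stimulus, fell in part in treated A673, but their list passed camera only at the preset correlation (adjusted p = 6.2e-35, but adjusted p = 0.159 with an estimated correlation). Of 30 measured, 18 fell and 0 rose (24 and 1 when adjusted over the list alone), with IER3 (-1.48), IER5 (-1.14), IER2 (-1.06) and DUSP2 as examples. DESeq2 called 14 of the 30. The untreated A673 libraries differed from each other in some members, such as FOSB (3809 and 6058 counts) and JUNB (2911 and 4369). DUSP2 had 387 and 568 counts untreated against 88 and 93 treated. Of 22 BMP and TGF-beta targets, 12 fell and 0 rose (12 and 1 adjusted over the list alone), among them the pathway inhibitor SMAD7 (-1.27), ID1 (-1.33) and ID3 (-0.87). That list kept its call with an estimated correlation (adjusted p = 5.8e-26 at the preset and 0.00845 estimated).

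Signalling lists beside these fell in part. Of 21 NF-kappaB and inflammatory genes, 4 fell (5 adjusted over the list alone), NFKBIA (-0.81), IL11, LIF (-2.84) and TNFAIP3 (-1.13), and the last 2 lost their call without A673 DOX+ replicate 1 (adjusted p = 0.0682 and 0.0795). The adjusted p for the list was 7.0e-08 with camera, but adjusted p = 0.166 with an estimated correlation. Of 19 FGF/ERK feedback genes, 7 fell, such as DUSP5 (-0.79) and DUSP6 (-0.73), and 2 rose, SPRY1 and SPRY2 (0.36); over the list alone 8 fell and 2 rose (adjusted p = 5.3e-07, but adjusted p = 0.166 with an estimated correlation). Of 18 NOTCH pathway genes, 6 fell, such as the target genes HES1 (-1.14) and NRARP (-0.93), and the receptor gene NOTCH2 rose (0.31); over the list alone 8 fell and 2 rose (adjusted p = 2.5e-05, but adjusted p = 0.190 with an estimated correlation). Of 21 YAP/TAZ targets, 7 fell, led by GADD45B and FJX1 (-0.55), with 10 lower and 1 higher adjusted over the list alone (adjusted p = 4.0e-06, but adjusted p = 0.142 with an estimated correlation). Of 14 WNT targets, MYC (-0.76) and BAMBI (-0.56) fell, 4 adjusted over the list alone (adjusted p = 0.0026, but adjusted p = 0.187 with an estimated correlation).

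All 13 mitochondrially encoded mRNAs had lower values in treated A673, and 12 of them fell, with a median log2 fold change of -1.27. MT-CO3 fell by 1.33 (SE 0.06), MT-CYB by 1.34 (SE 0.08), MT-CO1 by 1.11 (SE 0.07) and MT-ND5 by 1.22 (SE 0.08), whereas MT-ND3 was at -0.11 (SE 0.07, adjusted p = 0.43) and was chosen for naming after its value was seen. The list had 12 lower also when adjusted over the list alone, and kept its call with an estimated correlation (adjusted p = 2.2e-96 at the preset and 0.0238 estimated). The mitochondrial genome's share of all counts went from 2.08% and 1.98% in untreated A673 to 1.10% and 0.918% in treated A673, and was 1.96% and 2.02% untreated against 2.16% and 2.43% treated in UE7T-13.

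**Figure D3:**
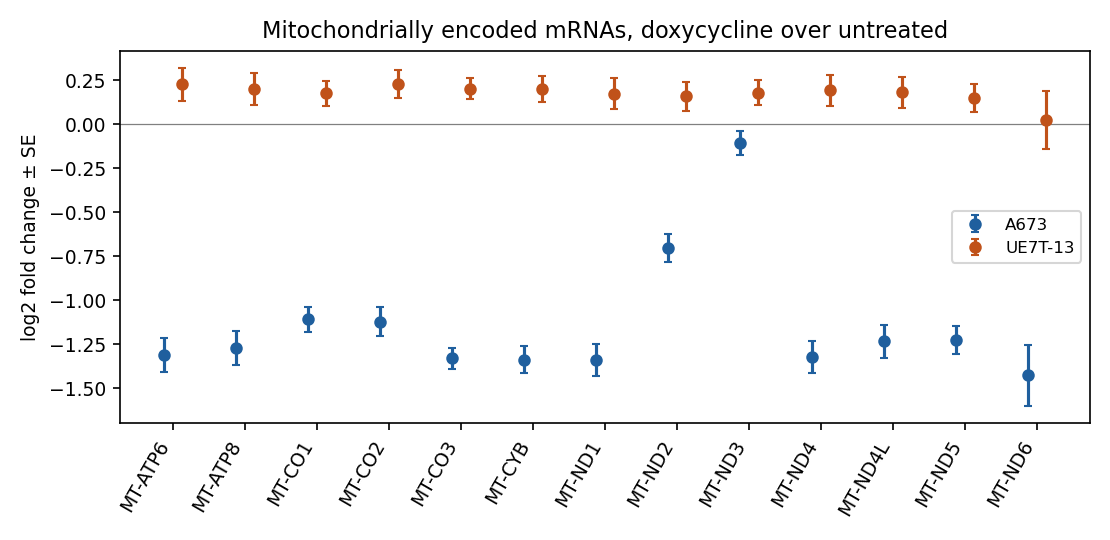
Log2 fold change with doxycycline (vertical axis, bars are SE) of the 13 mitochondrially encoded mRNAs in A673 and UE7T-13. The median was -1.27 in A673, with MT-ND3 at -0.11, and 0.18 in UE7T-13.

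The SOX family, 11 other members measured, fell with SOX2 induction in A673. SOX8 (-1.44), SOX9 (-1.02), SOX1 (-0.75) and SOX4 (-0.49) were among 6 members that fell, 7 when adjusted over the list alone, and 0 rose. The list kept its call with an estimated correlation (adjusted p = 1.0e-12 at the preset and 0.0226 estimated). Of 13 neural progenitor genes SOX1 alone fell, and 2 adjusted over the list alone (adjusted p = 0.0185, but adjusted p = 0.166 with an estimated correlation). Of 11 pluripotency genes, the partners and targets of SOX2 in stem cells, MYC and KLF4 (-1.28) fell and 0 rose, the same numbers over the list alone (adjusted p = 0.0895). KLF4 lost its call by DESeq2 (adjusted p = 0.0791). It also lost it without A673 DOX+ replicate 1 (-0.87) or A673 DOX- replicate 2 (-0.71).

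Proliferation genes were the only list that camera called higher in treated A673, at the preset correlation alone. Of 34, 5 rose and 0 fell (7 and 0 adjusted over the list alone): MKI67 (0.35), CENPF (0.20), CCNB1 (0.19), ASPM (0.19) and CENPE (0.22), the last chosen for naming after its value was seen. The list's median was 0.08 (adjusted p = 8.9e-06, but adjusted p = 0.166 with an estimated correlation), and MKI67, CCNB1, CENPF and ASPM lost their call without A673 DOX+ replicate 1 (adjusted p = 0.0782, 0.246, 0.157 and 0.275), the last 3 also without A673 DOX- replicate 2 (0.104, 0.123 and 0.141) and CENPF without A673 DOX+ replicate 2 (0.0800). With GC and length offsets ASPM was at 0.12 (adjusted p = 0.120) and CENPF at 0.14 (adjusted p = 0.0572), and both lost their calls. Of 27 doxorubicin resistance and drug efflux genes, the antiapoptotic genes MCL1 (-0.37) and BCL2L1 (-0.29) fell and 0 rose (3 and 2 adjusted over the list alone), with an adjusted p of 0.643 for the list by camera and 0.0237 (lower) by fry. BCL2L1 lost its call without A673 DOX+ replicate 1 (adjusted p = 0.0979). Of 24 p53 targets 7 fell, with the cell cycle inhibitor CDKN1A (-0.75), PHLDA3 (-0.97) and GADD45A (-0.63) among them, and over the list alone 10 fell and 2 rose (adjusted p = 2.6e-04, but adjusted p = 0.0997 with an estimated correlation).

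Genes under control of EWSR1-FLI1, the fusion that drives Ewing sarcoma, showed no shared direction. Of 27 activated genes, ID2 (-0.61), MYC, NKX2-2 (-0.48) and NR0B1 (-0.28) fell and PAPPA (0.23) rose, 6 and 1 adjusted over the list alone, with an adjusted p of 0.225; the list's median was 0.01 while its mean was -0.07. NR0B1 and PAPPA lost their calls without A673 DOX+ replicate 1, A673 DOX+ replicate 2 or A673 DOX- replicate 1. NR0B1 also lost its call without A673 DOX- replicate 2. With GC and length offsets NR0B1 was at -0.22 (adjusted p = 0.0744) and lost its call. Of 23 repressed genes, 4 fell, with IER3 and CDKN1A first, and SPRY1 and TPM1 (0.25) rose, 7 and 2 adjusted over the list alone (adjusted p = 0.0475, but adjusted p = 0.460 with an estimated correlation). TPM1 lost its call without A673 DOX+ replicate 1 (adjusted p = 0.111) or A673 DOX- replicate 2 (adjusted p = 0.0615).

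Stress and metabolic lists were lower in treated A673 at the preset correlation. Of 31 ATF4 and integrated stress response genes, 12 fell, such as ATF5 (-0.48) and CEBPB (-0.35), and CHAC1 rose (0.38), 17 and 2 adjusted over the list alone (adjusted p = 1.9e-08, but adjusted p = 0.190 with an estimated correlation). CHAC1 lost its call without A673 DOX- replicate 1 (adjusted p = 0.178) or A673 DOX+ replicate 2 (adjusted p = 0.189). Of 18 heat shock genes, 5 fell, with HMOX1 (-1.02) and the near-identical pair HSPA1A (-0.59) and HSPA1B (-0.57), 6 adjusted over the list alone (adjusted p = 4.0e-06, but adjusted p = 0.142 with an estimated correlation). Of 27 glycolysis and hypoxia genes, 5 fell, such as PFKFB3 (-0.55) and VEGFA (-0.60), 6 adjusted over the list alone (adjusted p = 5.4e-06, but adjusted p = 0.396 with an estimated correlation). Of 22 cholesterol synthesis genes, 5 fell, 12 adjusted over the list alone (adjusted p = 7.5e-06, but adjusted p = 0.306 with an estimated correlation).

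Lists for cell identity changed little in A673. Of 20 epithelial-mesenchymal transition genes, the repressors of epithelial genes SNAI1 (-1.04) and SNAI2 (-0.56) fell and ITGAV (0.38) rose, 3 and 1 adjusted over the list alone (adjusted p = 0.485), and ITGAV lost its call without A673 DOX+ replicate 1 (adjusted p = 0.161) or A673 DOX- replicate 2 (0.0619). Of 21 mesenchymal stromal markers, CD44 (-0.31) and NT5E (-0.26) fell, 4 adjusted over the list alone (adjusted p = 0.237), and both lost their calls without A673 DOX+ replicate 1 (adjusted p = 0.143 and 0.159), NT5E also without A673 DOX+ replicate 2 (0.0562) or A673 DOX- replicate 2 (0.0828). Of 19 osteogenic, chondrogenic and adipogenic genes, SOX9, MSX2 (-1.45) and CEBPB fell, and 3 adjusted over the list alone (adjusted p = 0.0388, but adjusted p = 0.166 with an estimated correlation). IRF1 (-0.63) was the only call among 24 interferon response genes (adjusted p = 0.595 for the list), and KRT18 (-0.20) among 10 epithelial markers (adjusted p = 0.306). Without A673 DOX+ replicate 1 or A673 DOX- replicate 2 both calls were lost. IRF1 also lost its call without A673 DOX+ replicate 2, and KRT18 without A673 DOX- replicate 1. With GC and length offsets KRT18 was at -0.14 (adjusted p = 0.0696) and lost its call. EdgeR called 0 of 18 unfolded protein response genes (adjusted p = 0.289), 24 histone genes (0.485), 5 blood and immune markers (0.688) and 9 endothelial markers (0.748), as did DESeq2, against 0, 3, 0 and 1 at an unadjusted p under 0.05.

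**Figure D4:**
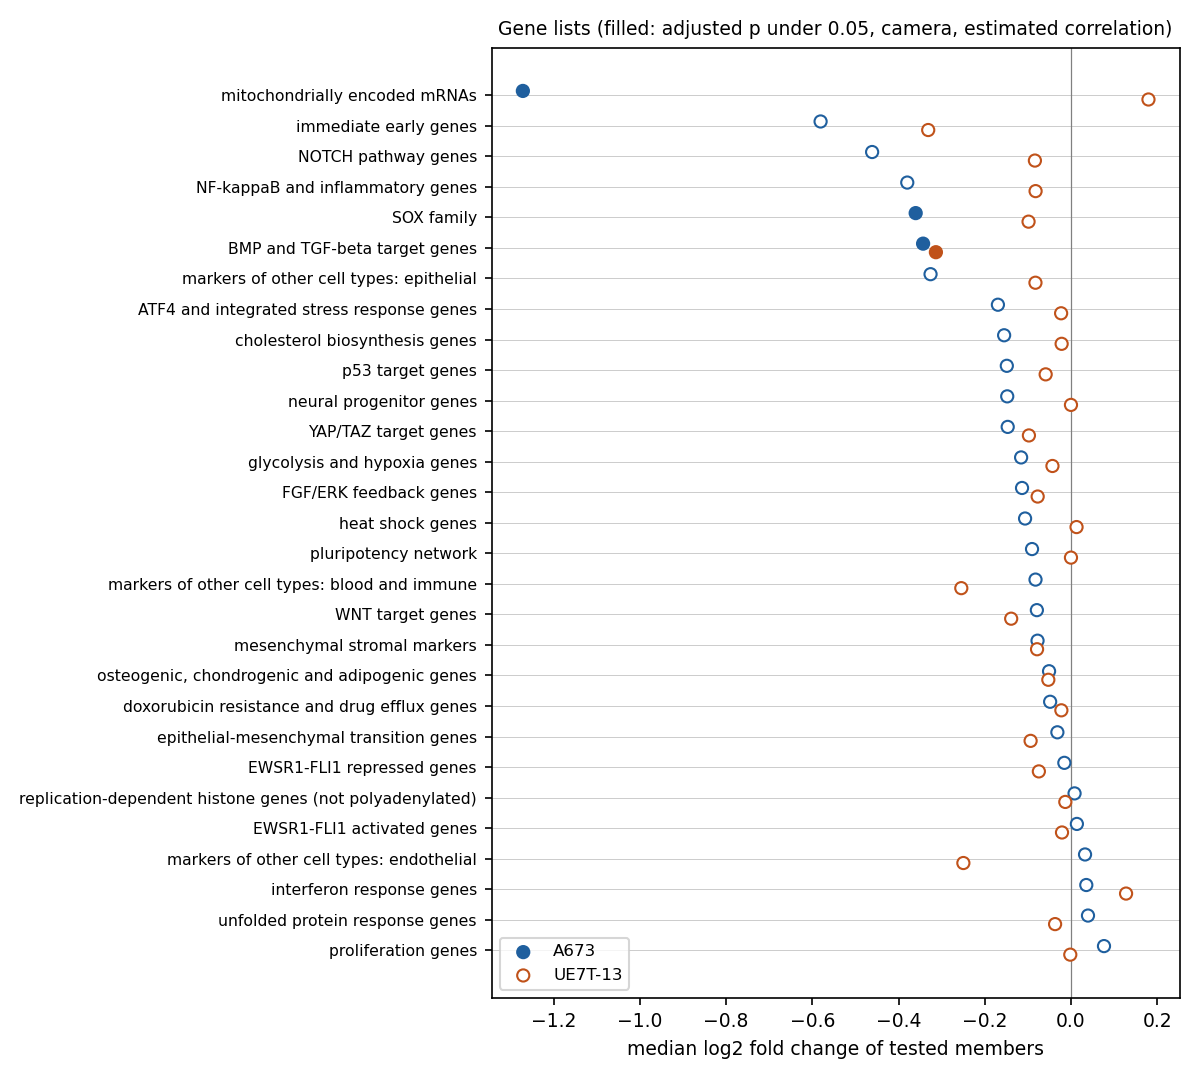
Median log2 fold change with doxycycline of the tested members of each of 29 gene lists (horizontal axis) in A673 (blue) and UE7T-13 (orange); filled points passed camera with an estimated correlation. In A673 the mitochondrially encoded mRNAs (-1.27), the SOX family (-0.36) and BMP and TGF-beta targets (-0.34) did, and in UE7T-13 BMP and TGF-beta targets (-0.31).

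In UE7T-13, the line of mesenchymal stem cells, doxycycline was followed by fewer changes, and again more genes fell than rose. DUSP1, a phosphatase of MAP kinases, fell by 1.24 (SE 0.15), the cytokine LIF by 1.04 (SE 0.08), BHLHE40 by 1.02 (SE 0.11), the NOTCH target HES1 by 0.97 (SE 0.12), SOCS3 by 0.97 (SE 0.12), GADD45B by 0.90 (SE 0.10), SMAD7 by 0.87 (SE 0.07) and the BMP target ID1 by 0.81 (SE 0.09). Also lower were the homeobox gene DLX3 (-0.81), RIPK4 (-1.26), FOSB (-1.16), MN1 (-1.03), JUNB (-0.82) and NFATC2 (-0.76). Of genes that rose beside SOX2, NFKBIZ (0.82, SE 0.10) and DKK1 (0.60, SE 0.08), a secreted inhibitor of WNT signalling, kept their calls in all 21 fits that tested them. The other named higher genes were PDE4D (1.25), KCNJ2 (1.10), ESM1 (0.60), MAB21L1 (0.60), ZNF813 (0.59), the sphingosine phosphate receptor S1PR1 (0.49), KBTBD6 (0.45), TLR4 (0.31), NEDD9 (0.29), KCNE4 (0.28) and PELO (0.26).

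Altogether 17 genes were higher and 114 lower in treated UE7T-13, 6 and 7 with a log2 fold change of at least 1. Leaving out any 1 UE7T-13 library, which leaves its group with 1 library, ended many of these calls. A lost call does not single out the library left out, since every such fit rests on fewer libraries. Without DOX- replicate 1, DOX- replicate 2, DOX+ replicate 1 or DOX+ replicate 2, the numbers higher were 7, 7, 11 and 7 and the numbers lower 60, 55, 74 and 46. Without those libraries 19, 21, 17 and 23 of the 46 genes named for this comparison or its lists lost their calls, which included the 11 named higher genes listed after NFKBIZ and DKK1, and RIPK4, FOSB, MN1, JUNB and NFATC2. Without A673 DOX- replicate 1 or replicate 2, 29 and 30 genes were higher.

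SOX1, a close relative of SOX2, had 0 counts in both untreated UE7T-13 libraries and 11 and 13 in the treated ones, at least 8.28-fold higher (adjusted p = 0.0010). BMP and TGF-beta targets fell as a group in UE7T-13 too: of 22, 8 fell and 0 rose, 12 and 0 adjusted over the list alone, with SMAD7, ID1, ID3 (-0.58), SKIL (-0.49) and ID2 (-0.54) among them (adjusted p = 5.9e-32 at the preset and 0.0054 with an estimated correlation). Of 30 immediate early genes, 7 fell and 0 rose, 14 and 1 adjusted over the list alone, with DUSP1 and IER3 (-0.51) as examples (adjusted p = 3.5e-21, but adjusted p = 0.325 with an estimated correlation). Of 21 YAP/TAZ targets, GADD45B, F3 (-0.43) and ANKRD1 (-0.32) fell, 8 adjusted over the list alone (adjusted p = 8.0e-12, but adjusted p = 0.105 with an estimated correlation). ANKRD1 lost its call without UE7T-13 DOX- replicate 1 (adjusted p = 0.197), DOX+ replicate 1 (0.112) or DOX+ replicate 2 (0.0803). Mitochondrially encoded mRNAs had a median of 0.18, with 0 of 13 called by edgeR, also over the list alone, 0 by DESeq2 and 7 at an unadjusted p under 0.05 (adjusted p = 6.3e-10, but adjusted p = 0.36 with an estimated correlation). Of the 34 proliferation genes and the 27 doxorubicin resistance genes, edgeR and DESeq2 called 0, against 0 and 1 at an unadjusted p under 0.05 (adjusted p = 0.900 and 0.927 for the lists).

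Further lists in UE7T-13 passed at the preset correlation and lost their call with an estimated one. Of 20 epithelial-mesenchymal transition genes SNAI2 (-0.76) fell, 1 adjusted over the list alone (adjusted p = 3.6e-04, but adjusted p = 0.228 with an estimated correlation). Of 18 NOTCH pathway genes HES1 and LFNG (-0.70) fell, 5 adjusted over the list alone (adjusted p = 7.2e-04, but adjusted p = 0.387 with an estimated correlation), and LFNG lost its call without UE7T-13 DOX+ replicate 2 (adjusted p = 0.321), DOX- replicate 1 (0.129) or DOX- replicate 2 (0.131). Of 19 FGF/ERK feedback genes 4 fell, with DUSP5 (-0.60) among them, and over the list alone 5 fell and 3 rose (adjusted p = 8.8e-04, but adjusted p = 0.36 with an estimated correlation). Of 31 ATF4 and stress response genes CEBPB (-0.64) and SLC7A5 (-0.30) fell, 4 adjusted over the list alone (adjusted p = 0.0050, but adjusted p = 0.550 with an estimated correlation), and SLC7A5 lost its call without UE7T-13 DOX+ replicate 1 (adjusted p = 0.0862) or DOX- replicate 1 (0.0989). Of 27 glycolysis and hypoxia genes VEGFA (-0.57) fell, the same number over the list alone (adjusted p = 0.0075, but adjusted p = 0.713 with an estimated correlation). Of 21 NF-kappaB and inflammatory genes LIF and IL11 (-0.69) fell and NFKBIZ rose, 6 and 1 adjusted over the list alone (adjusted p = 0.0107, but adjusted p = 0.520 with an estimated correlation), and IL11 lost its call without UE7T-13 DOX+ replicate 2 (adjusted p = 0.0861).

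Among the lists tied to the study in UE7T-13, 2 of 27 EWSR1-FLI1 activated genes fell, 4 and 1 higher adjusted over the list alone (adjusted p = 0.0043, but adjusted p = 0.228 with an estimated correlation). Of 23 repressed genes 1 fell and 1 rose, 6 and 3 adjusted over the list alone (adjusted p = 0.0263, but adjusted p = 0.534 with an estimated correlation). SOX1 was the only call among the other SOX family members (adjusted p = 0.927 for the list) and among 13 neural progenitor genes (adjusted p = 0.205). Of 21 mesenchymal stromal markers edgeR called 0 and DESeq2 2, against 4 at an unadjusted p under 0.05 and 3 lower adjusted over the list alone (adjusted p = 4.1e-04, but adjusted p = 0.237 with an estimated correlation). Of 24 interferon response genes both tools called 0, against 2 at an unadjusted p under 0.05 (adjusted p = 0.0375 for a higher list, but adjusted p = 0.771 with an estimated correlation). Of 19 osteogenic, chondrogenic and adipogenic genes 1 fell (adjusted p = 0.0116, but adjusted p = 0.228 with an estimated correlation). In all, camera called 13 lists lower and 2 higher at the preset correlation, and BMP and TGF-beta targets alone with an estimated one.

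The overlap of the responses asks which genes answered doxycycline in both lines. Lower in both were 80 genes, where 4.85 would be shared by independent lists of the same sizes, and higher in both were 6, where 0.269 would be: SOX2, NEDD9, TLR4, S1PR1, KBTBD6 and PELO. The 80 include these genes, chosen from them after their values were seen: IL11, LIF, CLCF1, SOCS3, BHLHE40, GADD45B, PDGFA, SMAD7, ID1, HES1, MYC and VEGFA. In UE7T-13 MYC kept its call in 19 of 21 fits and IL11 in 20, and in A673 LIF kept its call in 19 of 21. The median fall of the 80 genes was larger in A673 (-0.75) than in UE7T-13 (-0.51), and 14 of them had a larger fall in A673 by the test of the difference. In opposite directions, LMO4, SPRY2 and AKAP13 were higher in A673 and lower in UE7T-13, and KCNE4 and SOX1 were lower in A673 and higher in UE7T-13, where independent lists would share 1.81 and 0.724. These 5 were chosen for naming after their values were seen. SPRY2 kept its UE7T-13 call in 14 of 21 fits and lost it without UE7T-13 DOX- replicate 1 (adjusted p = 0.129), DOX- replicate 2 (0.401), DOX+ replicate 1 (0.168) or DOX+ replicate 2 (0.373), without A673 DOX+ replicate 1 (0.05004) and with library totals (0.0684), among others. The lines use different untreated libraries, so no control is shared. Across all 20946 genes the log2 fold changes of the lines had a Pearson correlation of 0.0369, against 0.144 across 11267 well-expressed genes. It was 0.205 across the 1224 genes called in A673 and 0.512 across the 131 called in UE7T-13. These last 2 sets were picked by the fold changes themselves, and genes are not independent replicates. SOX2, induced by design in both lines (5.94 and 4.95), is in every set, and its share of the correlations was not tested.

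**Figure D5:**
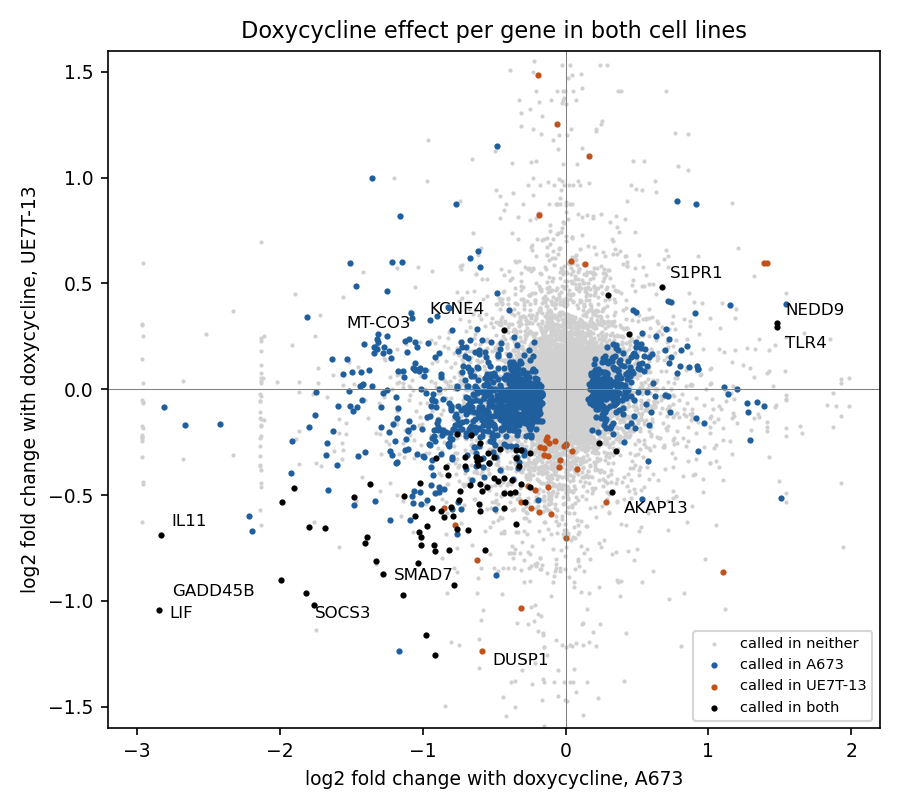
Log2 fold change with doxycycline in A673 (horizontal axis) and UE7T-13 (vertical axis) for genes with at least 1 CPM in the highest group; SOX2 and SOX1 lie outside the axes. The 80 genes called lower in both lines lie at the lower left, with IL11 at -2.83 and -0.69 and LIF at -2.84 and -1.04.

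The difference between the effects in A673 and in UE7T-13 was tested for each gene. NEDD9 rose more in A673 (difference 1.19, SE 0.08, adjusted p = 1.9e-06), and so did SOX2 itself (0.99, SE 0.12, adjusted p = 0.00035). IL11 fell more in A673 (-2.15, SE 0.24, adjusted p = 0.00020), as did the 12 mitochondrially encoded mRNAs called in A673, such as MT-CO3 (-1.53, SE 0.09). Further genes higher in A673 by this test included AKAP13 (0.81), MIR7705 (1.22), CHAMP1 (0.74) and RGS4 (0.81), and those lower included TRIM47 (-1.67), NFKBID (-1.64), MT-TV (-1.63), MT-TM (-1.95) and RIMBP3 (-1.67). IER5 (-1.22), GADD45B (-1.09) and CDKN1A (-0.58) also fell more in A673. RGS4 lost its call without A673 DOX+ replicate 1 (adjusted p = 0.0618), and RIMBP3, which has near-identical copies, without that library (0.0585) or UE7T-13 DOX+ replicate 1 (0.0581).

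By this test 52 genes were higher and 171 lower in A673, and without A673 DOX+ replicate 1 15 and 98. Without UE7T-13 DOX- replicate 2 the counts were 17 and 105, without UE7T-13 DOX+ replicate 1 107 were lower, and without UE7T-13 DOX+ replicate 2 19 were higher. Of the lists, the mitochondrially encoded mRNAs kept their call with an estimated correlation, with 12 of 13 lower, 13 adjusted over the list alone, and a median difference of -1.45 (adjusted p = 1.8e-133 at the preset and 0.0389 estimated). Of 30 immediate early genes, 3 were lower, 10 when adjusted over the list alone with 1 higher (adjusted p = 1.8e-09, but adjusted p = 0.386 with an estimated correlation). For BMP and TGF-beta targets 2 of 22 were lower, 6 adjusted over the list alone (adjusted p = 0.0022, but adjusted p = 0.173 with an estimated correlation), with a median difference of -0.08 and a mean of 0.03. Of the 34 proliferation genes edgeR called 0 by the difference and DESeq2 1, against 7 at an unadjusted p under 0.05, with 1 higher adjusted over the list alone (adjusted p = 9.9e-05, but adjusted p = 0.336 with an estimated correlation).

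Untreated A673 and UE7T-13 were compared as background, and cell line and tissue of origin cannot be separated there. A673 had 28864 counts of the prohormone convertase PCSK2, 17930 of the netrin receptor DCC and 19881 of OLFM3 where UE7T-13 had 0, at least 8848-fold, 5496-fold and 6095-fold higher. ITM2A was at least 25029-fold, CES1 at least 18002-fold, HOOK1 at least 13499-fold, CLVS2 at least 5341-fold, JAKMIP2 at least 4954-fold and CYYR1 at least 4561-fold higher in A673. NELL2 had 94003 counts in A673 and 1 in UE7T-13, a ratio of 86450 (95% counting interval 15516 to 3414587). UE7T-13 had 292837 counts of the cartilage proteoglycan ACAN, 59335 of the growth factor FGF5, 36633 of the hyaluronan synthase HAS2 and 9531 of the cell cycle inhibitor CDKN2A where A673 had 0, at least 106141-fold, 21506-fold, 13278-fold and 3455-fold higher. ATP10A was at least 6103-fold, FAM180A at least 4671-fold, HSPB7 at least 2955-fold, APBB1IP at least 2801-fold and SLC8A1 at least 2619-fold higher in UE7T-13. The BMP antagonist GREM1 had 483229 counts in UE7T-13 and 19 in A673, a ratio of 27655 (interval 17709 to 45934). In all, 8432 genes were higher in A673 and 8075 in UE7T-13, and the direction of calls near the threshold depends on the scaling, since library totals moved the median log2 fold change of all genes from 0.05 to 0.31 and turned 38 calls.

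The authors' own tables, at an adjusted p under 0.05, hold 217 genes higher and 652 lower in treated A673, and 25 higher and 172 lower in treated UE7T-13. Of the 59653 rows in each, 44425 for A673 and 44646 for UE7T-13 have no adjusted p, and these were counted as not called there. TLR4, TINAGL1 and LIF in A673 are among them. Of the 1221 genes called here in A673 that could be matched by symbol, 818 are also called there in the same direction (67.0%, exact 95% interval 64.3 to 69.6), and in UE7T-13 119 of 131 (90.8%, 84.5 to 95.2). These intervals treat genes as independent, although they share the same libraries, and can be too narrow. Of the authors' calls that could be matched, 94.2% of 868 in A673 and 60.7% of 196 in UE7T-13 are also called here. Among called genes 0 had the opposite direction in either line. The authors' table gives SEMG1 in A673 a log2 fold change of -2.45 for untreated over doxycycline, with an SE of 0.49 and an adjusted p of 3.8e-05 from DESeq2, and SOX2 -5.94.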

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

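The tests for dilution by SOX2 reads, for lower mitochondrial yield, for doxycycline acting alone and for both sources of SOX1 were chosen only after the result was seen. The single genes, the 2 counts of genes and the mitochondrial median in this part were singled out because the effect of doxycycline differed between A673 and UE7T-13 by a test of the difference itself. The GC-rich lower genes and those lower in both lines were weighed because fold changes in A673 followed GC content.

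The effects of 52 genes were higher and of 171 lower in A673. For SOX2 the difference was 0.99 (SE 0.12), for NEDD9 1.19 (SE 0.08), for AKAP13 0.81, for CHAMP1 0.74 and for MIR7705 1.22. These 5 kept their calls in all 20 fits that tested them, 19 for SOX2, which 1 fit left out. RGS4 differed by 0.81 and lost its call without A673 DOX+ replicate 1 (adjusted p = 0.0618). TLR4 differed by 1.17 and lost its call without A673 DOX+ replicate 1 (adjusted p = 0.233), A673 DOX- replicate 2 (0.142), UE7T-13 DOX+ replicate 2 (0.0672), UE7T-13 DOX- replicate 1 (0.0516) or UE7T-13 DOX- replicate 2 (0.0617). KBTBD8 differed by 1.16 and lost its call without A673 DOX+ replicate 1 (adjusted p = 0.257), A673 DOX- replicate 2 (0.114) or any 1 UE7T-13 library. EFEMP1 differed by 1.40 and lost its call without A673 DOX+ replicate 2 (adjusted p = 0.141), A673 DOX- replicate 1 (0.0578) or A673 DOX- replicate 2 (0.0612). SYT16 differed by 4.52, with 1 and 0 counts in untreated and 14 and 4 in treated A673, and lost its call without A673 DOX+ replicate 1 (adjusted p = 0.438), without any 1 of the other 7 libraries except A673 DOX+ replicate 2, with GC offsets (adjusted p = 0.0609) and by DESeq2 (0.0572).

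Effects lower in A673 were those of IL11 (-2.15, SE 0.24), TRIM47 (-1.67), NFKBID (-1.64), MT-TV (-1.63) and MT-TM (-1.95), which kept their calls in all 20 fits that tested them. RIMBP3 (-1.67) lost its call without A673 DOX+ replicate 1 (adjusted p = 0.0585) or UE7T-13 DOX+ replicate 1 (0.0581). GPRC5A (-1.73) lost its call without A673 DOX+ replicate 1 (adjusted p = 0.212), DOX+ replicate 2 (0.0523) or DOX- replicate 2 (0.0893), or without UE7T-13 DOX+ replicate 2 (0.0785) or DOX- replicate 2 (0.0784). PIK3C2B (-1.68) had 9 and 10 counts in untreated and 27 and 26 in treated UE7T-13, and lost its call without any 1 UE7T-13 library. MIR6821 (-2.10), which lies within a longer transcript, lost its call without A673 DOX+ replicate 1 (adjusted p = 0.115), without any 1 of the other 7 libraries except A673 DOX+ replicate 2, and with GC offsets (0.0685).

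SOX1 was at least 8.28-fold higher with doxycycline in UE7T-13, with 0 and 0 counts untreated and 11 and 13 treated, while it fell by 0.75 (SE 0.07) in A673. RNA or reads of A673 in the UE7T-13 libraries were argued against. A share of 0.536% would be needed for these counts and would also bring 457 counts of NELL2, 392 of ITM2A and 261 of CES1, and the 3 genes together had 3. SOX2 reads counted on its relatives as a class were argued against too, since SOX3, SOX14 and SOX21 together had 0 counts in the 4 treated libraries. The more distant SOX15, chosen after its counts were seen, had 3 and 3 counts in untreated and 7 and 11 in treated UE7T-13, but 2 and 9 in untreated and 2 and 4 in treated A673, where SOX2 reads were more numerous. SOX2 reads placed on SOX1 alone stay open, with 24 SOX1 counts beside 121809 and 111173 SOX2 counts in treated UE7T-13, and so does a start of transcription of SOX1 after SOX2 induction, which was not tested apart from it.

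The median effect on the 13 mitochondrially encoded mRNAs was 1.45 lower on the log2 scale in A673 than in UE7T-13 (-1.45). A trend with GC content and length was argued against as the whole cause, since the median in A673 was -1.35 with offsets for both, against -1.27 without. A single aberrant A673 library was argued against, since the highest median over the 4 fits that each leave out 1 A673 library was -1.10, with 12 called in each. Dilution by SOX2 reads was argued against by their share, 1.2% and 1.3% of all counts in treated A673. That share is too small to lower other genes by as much as the mRNAs' median of -1.27. Scaled by library totals alone, the median of all tested genes in A673 was 0.00248. At that share this median could not have come out otherwise, so it adds no support. A lower yield of mitochondrial RNA as a whole stays open, because the answer depends on MT-ND3, the most extreme member. Without it the mRNAs spanned a range of 0.723, from -1.43 to -0.70, and with it 1.32. A loss by the same factor for all would not account for MT-ND3, at -0.11 (SE 0.07). Doxycycline acting on mitochondria without SOX2 stays open, since 0 libraries had doxycycline and no SOX2 construct, and an effect of SOX2 cannot be told apart from it.

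Genes lower in treated A673 were GC-rich, with a median GC content of 58.0% against 48.7% for all tested genes. With offsets for GC content and length, 605 of the 892 lower genes were still called lower (67.8%, exact 95% interval 64.6 to 70.9). The intervals in this paragraph treat genes as independent, although they share the same libraries, and can be too narrow. The median log2 fold change of these 605, which were picked by that outcome, went from -0.58 to -0.50. For the 287 others the median log2 fold change went from -0.32 to -0.18 and the median SE from 0.0748 to 0.0667, so the calls ended because the folds shrank. How far the falls of the 892 come from the libraries' GC trend and how far from the cells cannot be told apart, because the treated libraries also differ from the untreated ones in the trend. Of the 80 genes lower in both lines, 76 were still lower in both (95.0%, 87.7 to 98.6), which argues against the trend as the whole cause of the shared falls, and a response to SOX2 or to doxycycline itself remains open for them.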

How the results depend on the processing

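The GC and length offsets, alone and with an estimated correlation, were chosen only after the data were seen. Of the genes named by the rule, 0 turned in direction in any fit. Library totals turned 38 calls between untreated lines, and the direction of some lists without a call turned, such as the NOTCH list for the difference with GC and length offsets (adjusted p = 0.884).

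Without a filter on low counts, 513 genes were higher in A673, 86 were higher and 282 lower in UE7T-13, and 235 were higher and 434 lower by the difference; the cause was not tested. With a log2 fold change of at least 1, 21 were higher and 140 lower in A673, 6 and 7 in UE7T-13, 8 and 59 by the difference, and 4598 and 5063 between untreated lines, since the threshold admits fewer genes. By DESeq2 103 were higher by the difference, and by limma-voom 25 were higher and 111 lower; the cause was not tested.

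With an estimated correlation, 3 lists were lower and 0 higher in A673, 1 and 0 in UE7T-13, and 1 and 0 by the difference, and GC and length offsets with an estimated correlation gave the same numbers (3 and 0, 1 and 0, 1 and 0). Fry called 15 lists lower and 1 higher in A673, 2 lists lower and 0 higher in UE7T-13, and 1 and 0 by the difference. At an unadjusted p under 0.05, 73 genes were higher and 322 lower in both lines. Among genes with a log2 fold change of at least 1, 60.2% of the calls here were also in the authors' table for A673 and 69.2% for UE7T-13. Genes without an adjusted p there were counted as not called, and the cause of the difference was not tested.

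When each library was left out in turn, the lone library of its group was assumed to vary like the others. The counts ranged from 71 to 282 higher and 367 to 822 lower in A673, 7 to 30 and 46 to 135 in UE7T-13, and 15 to 61 and 98 to 229 by the difference, with fewer libraries in each fit. The lowest A673 and difference counts came without A673 DOX+ replicate 1. With GC and length offsets 374 genes were higher and 685 lower in A673, 19 and 117 in UE7T-13, and 67 and 163 by the difference.

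SEMG1 in A673 kept its call in 20 of 21 fits, up to an adjusted p of 0.0354 without A673 DOX+ replicate 1, while DESeq2 gave it an unadjusted p of 1.7e-05 and no adjusted p, since its filter on mean counts set the gene aside. Of the genes named by the rule, 66 of 102 in A673, 22 of 47 in UE7T-13, 28 of 51 by the difference and 20 of 20 between untreated lines kept their call in every fit that tested them.

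Replicate numbers did not pair the samples: the deviations from group means of same-numbered libraries, treated against untreated, had a correlation of -0.0150 in A673 and 0.0216 in UE7T-13. With replicate number as a block, 319 genes were higher and 891 lower in A673, 24 and 129 in UE7T-13, and 59 and 203 by the difference. Genes with few counts are limited by depth: 3 counts in a library stand for 0.0575 to 0.0691 CPM.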

Other observations

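The genes in this part were chosen after their values were seen, and no explanation was tested for them.

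IL11, CLCF1 and LIF, 3 cytokines of the interleukin 6 family, fell in both lines, while IL6 itself was not called in either, with 1 and 3 counts in untreated and 5 and 5 in treated A673 and 101 and 116 against 100 and 103 in UE7T-13. IL11 went from 229 and 268 counts to 22 and 38 in A673 and from 2358 and 2202 to 1511 and 1286 in UE7T-13. CLCF1 went from 139 and 121 to 33 and 27 in A673 and from 3240 and 2986 to 2326 and 2133 in UE7T-13. LIF, at 36 and 49 counts in untreated and 4 and 6 in treated A673, went from 7877 and 8992 to 4337 and 3776 in UE7T-13. LIF in A673 lost its call without A673 DOX+ replicate 1 (adjusted p = 0.0682), and IL11 in UE7T-13 without UE7T-13 DOX+ replicate 2 (adjusted p = 0.0861). The fall of IL11 was larger in A673 by the test of the difference (-2.15).

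Counts of mitochondrial genes beside those of the mRNAs were lower in treated A673. The 2 ribosomal RNAs MT-RNR1 (-0.67) and MT-RNR2 (-0.72) fell, and 10 of 18 tested tRNA genes fell, with a median log2 fold change of -1.22 over the 18. In UE7T-13 edgeR and DESeq2 called 0 of these 20 genes, with 0 at an unadjusted p under 0.05, and the medians were 0.08 for the tRNAs and 0.08 for the ribosomal RNAs. Reads of mitochondrial genes cannot be told with certainty from those of nuclear copies. The tRNA genes are short, such as MT-TL1 at 75 bp, against 150 bp reads of polyadenylated RNA. Their counts can therefore include reads of adjoining transcripts, and a fall of the mature tRNAs was not tested.

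The glucocorticoid-induced kinase gene SGK1 fell in A673, from 13133 and 12904 counts to 6055 and 6208, and had 5183 and 5014 untreated against 5368 and 5225 treated counts in UE7T-13 (adjusted p = 1.9e-06 for the difference). FLI1 reads, which include those of the fusion, numbered 4872 and 4475 in untreated and 3949 and 3922 in treated A673. These counts are not scaled, and the totals of the same libraries went from 52143970 and 49041908 to 43502952 and 43433187. The raw counts alone therefore do not show a fall of FLI1. The nuclear receptor gene NR0B1 had 0 and 0 counts in untreated and 4 and 2 in treated UE7T-13 and was not called there.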
